A study of Homo sapiens with 6 samples.

How the data were processed

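RNA was measured by sequencing in 6 cultures of Ls174t, a human colorectal adenocarcinoma line that secretes mucin. Per the labels, a vector control line and a stable line overexpressing RNF186 were each divided into 3 dishes of 6 cm and collected without treatment after 48 h in DMEM with 10% fetal bovine serum and 1% penicillin-streptomycin. The 3 dishes of a group therefore came from 1 line, and every p-value measures the spread between dishes of 1 line, not between independently made lines. Libraries were made from total RNA with an Illumina TruSeq RNA kit, per the labels' protocols.

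The values are FPKM (fragments per kilobase of gene, scaled to the number of mapped fragments) as deposited by the authors, given to 2 decimals. The aligner named is Bowtie 0.12.2 and the genome builds named are the mouse builds mm8 and mm9, per the submitters' processing notes. These builds contradict the human organism label and the human gene identifiers of the table, and the extraction protocol in the labels speaks of retinas. Which build and annotation the deposited values rest on therefore stayed open, and no coordinates are printed. The counting program, the annotation and the treatment of reads shared by near-identical genes were not given in the sources used here. Values of single members of families with similar sequence, such as the metallothioneins, CXCL1, CXCL2 and CXCL3, HSPA1A and HSPA1B, and the CEACAM, IFITM, AKR1C and HLA genes, are uncertain for that reason.

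Of the 19485 rows of the table, 1 named no gene and was left out. Another 1921 gene rows had no value in any library and were left out, and 17563 rows had values. Gene symbols were assigned by Entrez identifier from the RefSeq gene table of assembly GRCh38.p14, used for names only, and 17524 rows matched while 39 did not. No symbol was repeated. Of the rows with values, 98.47% were protein coding, and 476 genes were at 0 in all 6 libraries.

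Read counts cannot be taken from FPKM without gene lengths and library totals, so the depth of each library is unknown and no counting interval is given. Low values were examined for steps of single reads. Among 659 pairs of low values of the same gene in different libraries, 33.38% lay within 0.15 of each other on the log2 scale, against 6.98% in the next window of the same width. Low values thus tend to recur across libraries, but this gives no absolute depth.

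Values were analysed as log2(FPKM + 1) for the 11632 genes with a mean of at least 1 FPKM over the 6 libraries. Groups were compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend, two-sided, no covariates), and p-values were adjusted by the Benjamini-Hochberg method over all tested genes. A gene is called at an adjusted p under 0.05. Changes are on the log2(FPKM + 1) scale, which understates the change of genes at low values. Ratios of means are ratios of FPKM. Intervals of a change are 95% intervals from the same model. An exact permutation test of 3 against 3 cannot go below a two-sided p of 0.1.

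Before the data were examined, 32 gene lists were fixed for a colorectal epithelial line, the topic of the series and other cell types. The 25 lists outside the other cell types with at least 5 tested members were compared with all other genes by camera in limma with a preset correlation of 0.01, adjusted over these lists. Camera with an estimated correlation and fry were alternatives. Members of a list are also counted with p-values adjusted over the list alone. The list of mitochondrially encoded genes had no measured member.

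The rule for named genes was also fixed beforehand. It takes RNF186, EPHB2, TNF and TNFRSF1A, the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, leaving out RNF186. It then takes up to 4 called members of each list with the smallest p, 2 members of a list with no called member, and the highest member of each list of another cell type. All other genes named in the text, and the 8 gene families in the closing section, were chosen after their values were seen.

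Alternatives were other pseudocounts and filters, median, quantile and TPM scaling, other variance models, array weights, a replicate block, leaving out each library, stricter thresholds, other set tests and lists without the member that changed most. A correction of each library for transcript length and GC content, taken from GENCODE release 29, was added after seeing the data. A count-based test was not run because the files hold no counts.

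The procedure was tested on simulated data for the comparison of RNF186 overexpression with vector over 11632 genes. Of 100 genes changed by 0.5 on the log2 scale 73% were called, and of 100 genes changed by 1 it was 96%, and 1.17% of the calls were genes that had not been changed. A simulated shift of 0.3 in a list of 15 genes was called (camera, adjusted p = 7.06e-27). Noise was drawn independently for each gene, and in the list simulation no gene outside that list was changed. The simulations therefore do not show how the tests behave with correlated genes or with changes as widespread as those reported below. Tables were joined with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.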

Results

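The transcriptome of Ls174t colorectal cancer cells was profiled in 3 vector cultures and 3 cultures overexpressing RNF186, a RING-type E3 ubiquitin ligase of the intestinal epithelium. Summed FPKM per library ran from 387477.6 to 412391.1, and 11510 to 11686 genes reached 1 FPKM. The 10 highest genes took 5.90 to 6.74% of the summed FPKM. Across genes, libraries correlated at r = 0.9962 to 0.9975 within the vector group, 0.9936 to 0.9974 within the RNF186 group and 0.9732 to 0.9792 between groups. The leading principal component held 79.9% of the variance and separated the groups, and the next held 10.1%. On the latter, RNF186 replicate 2 lay at 12.09 and the other libraries between -5.59 and 4.64. Values below are mean FPKM ± SD (n = 3 dishes per group), and adjusted p-values of genes are from limma.

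The comparison asks how RNF186 overexpression alters gene expression in these cells, with EPHB2 and TNF signalling named as the topic of the series. RNF186 (Entrez 54546) was 0.67 ± 0.0529 in vector cells and 505 ± 65.2 in RNF186 cells, a ratio of 753 (log2 change 8.23, SE 0.082, adjusted p = 3.43e-12), as the labels say. EPHB2 (Entrez 2048), a receptor tyrosine kinase for ephrin-B ligands, was 18.6 ± 0.767 against 18.2 ± 0.544. Its change of -0.03 had a 95% interval from -0.15 to 0.08 and did not pass the test (adjusted p = 0.643). TNF (Entrez 7124), the cytokine itself, rose from 0.187 ± 0.11 to 2.43 ± 0.101 (log2 change 1.54, SE 0.094, adjusted p = 1.69e-06). TNFRSF1A (Entrez 7132), its main receptor on epithelial cells, fell from 27.3 ± 0.431 to 22.7 ± 1.21 (log2 change -0.26, SE 0.053, adjusted p = 0.00424).

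**Figure D1:**
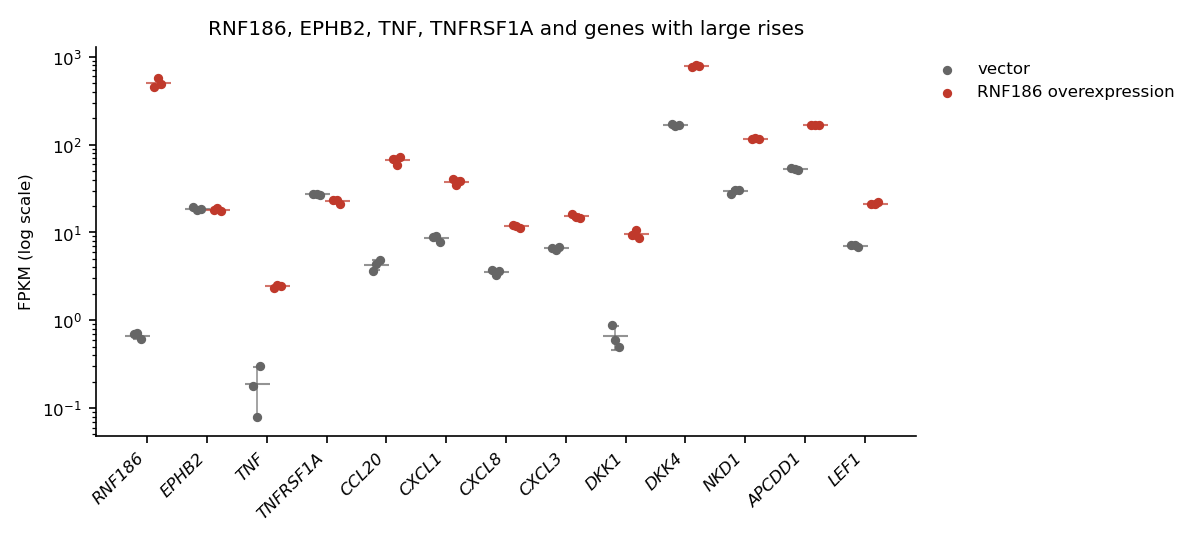
FPKM on a log axis for 13 genes in the 3 vector dishes (grey) and 3 RNF186 dishes (red), with points for dishes, a dash for the mean and bars for the SD. EPHB2 values of the groups overlap, and those of the other genes do not.

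On the log2(FPKM + 1) scale the largest rise after RNF186 was in CCL20, a chemokine of mucosal epithelium, from 4.31 ± 0.591 to 66.4 ± 6.9 (log2 change 3.67, adjusted p = 4.75e-09). Complement component C3 (log2 change 2.96), the morphogen SHH (2.73), the class II invariant chain CD74 (2.70) and the ubiquitin-like modifier UBD (2.70) followed. By ratio of means UBD (72.5) and C3 (18.1) stood above CCL20 (15.4). The vector means of UBD and C3 were only 0.0833 and 0.66 FPKM, so the sizes of these ratios are uncertain. The secreted WNT antagonists DKK1 (2.66) and DKK4 (2.23) also rose, DKK4 from 167 ± 4.93 to 789 ± 24.3. The other rises among the 12 largest were PI3 (2.37), IGFN1 (2.22), EDN3 (2.19), NELL2 (2.11) and the growth factor FGF20 (2.11). Metallothioneins, small proteins that bind zinc and copper, made up 7 of the 12 largest falls. MT1G fell from 824 ± 64.5 to 67.8 ± 5.15 (log2 change -3.58, adjusted p = 5.54e-10) and MT2A from 756 ± 95.6 to 100 ± 4.74 (-2.89, adjusted p = 6.09e-09). MT1M (-4.54), MT1F (-3.68), MT1H (-3.58) and MT1A (-2.19) fell as well, and MT1B, at 3.65, 2.19 and 4.76 FPKM in the vector libraries, was listed at 0 in the 3 RNF186 libraries. How reads shared by these similar genes were divided is not given in the sources used here, so single members are uncertain. The remaining large falls were the galectin LGALS1 (-2.67), the carbonic anhydrase CA9 (-2.61), LCN15 (-2.40), DHRS2 (-2.36) and COXFA4L2, formerly NDUFA4L2 (-2.24).

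In all, limma called 4509 of 11632 genes (38.8%), 2314 higher and 2195 lower with RNF186. Most changes were small, with a median size of 0.30 on the log2 scale, and 157 rises and 34 falls reached 1. The groups did not overlap for 49.5% of the genes, where chance gives 10%. The share of calls that were higher was 51.3%, 63.1% after rescaling to TPM and 43% of 5708 calls after a correction for length and GC content that was chosen after seeing the data. The number of lower genes was 1435 without RNF186 replicate 3. Across genes, which are not independent replicates, the change had a Spearman correlation of -0.29 with GC content, and length and GC content together held a share of 0.0504 of its variance.

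**Figure D2:**
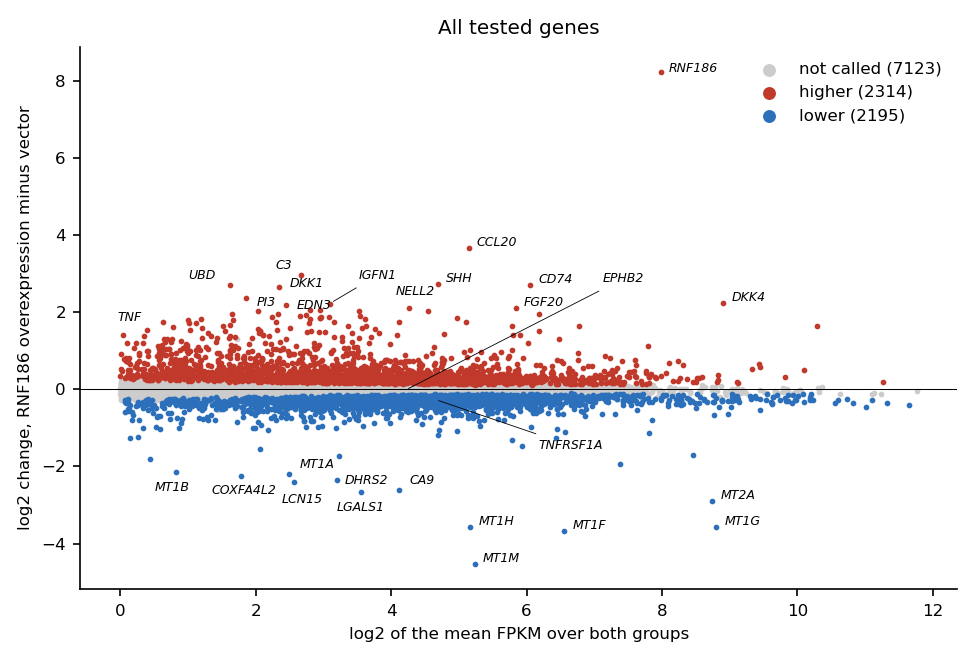
Log2 change (RNF186 overexpression minus vector) against the log2 of mean FPKM for the 11632 tested genes with 2314 called higher in red, 2195 called lower in blue and the others in grey. RNF186 lies at 8.23, and metallothioneins hold the lowest positions.

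**Figure D3:**
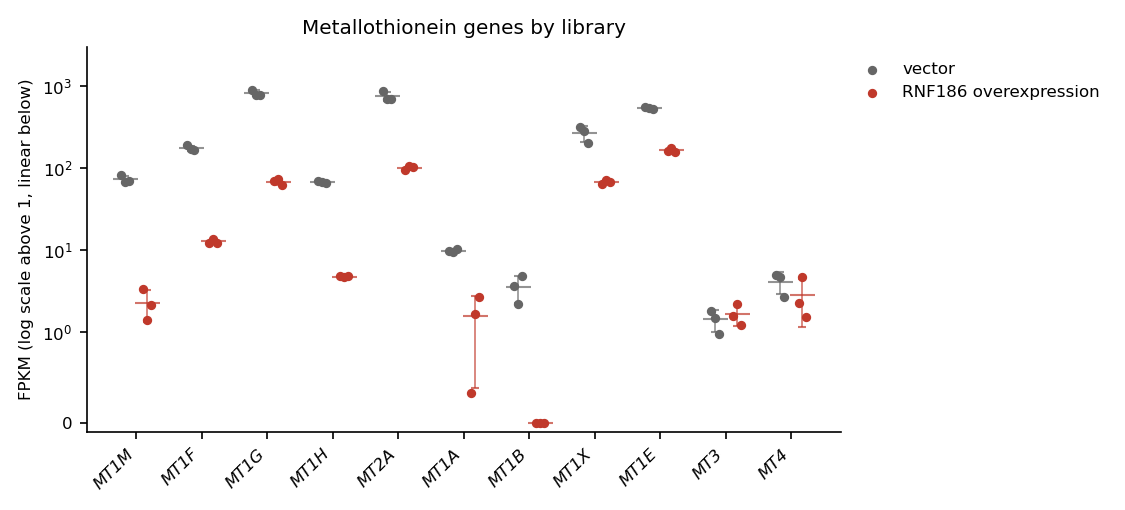
FPKM of 11 metallothionein genes by dish, on an axis that is logarithmic above 1 and linear below, with points for the 3 vector (grey) and 3 RNF186 (red) dishes, a dash for the mean and bars for the SD. The groups overlap for MT3 and MT4, and for the other 9 genes the RNF186 dishes lie lower.

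Targets of NF-κB, the transcription factor that acts downstream of TNF receptors, rose as a group. Of 31 tested members 24 rose and 7 did not pass, with a median change of 0.40 (camera, adjusted p = 3.77e-12, and 0.0192 with an estimated correlation). The chemokine CXCL1 rose from 8.58 ± 0.664 to 38 ± 3.41, CXCL8 from 3.56 ± 0.246 to 11.8 ± 0.392 and CXCL3 from 6.6 ± 0.232 to 15.3 ± 0.923, with the split between CXCL1 and CXCL3 uncertain for the same reason. The feedback inhibitors TNFAIP3 (2.87 ± 0.355 to 6.99 ± 0.26) and NFKBIA (20.4 ± 0.718 to 33.7 ± 1.25) rose too. The receptors, adaptors and kinases of the TNF pathway did not differ from other genes as a group (median 0.03, camera, adjusted p = 0.921). Of its 32 members 3 rose, MAP3K8 (0.59), MAP2K6 (0.43) and TRAF5 (0.39), and 4 fell, TRAF2 (-0.41), MAP2K3 (-0.35), MAP2K7 (-0.30) and TNFRSF1A. The call of MAP2K7 ended without vector replicate 2 (limma, adjusted p = 0.0505). Ephrins and their receptors did not move as a group either (15 tested, median -0.10, mean 0.00, camera, adjusted p = 0.522). EPHB6 (0.75), EPHA4 (0.50) and EPHB3 (0.31) rose, and EPHA1 (-0.34), EFNB2 (-0.33) and EPHA2 (-0.25) fell.

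Targets of WNT signalling, the pathway that sustains intestinal crypt cells, had 19 rises and 4 falls among 29 tested members (median 0.31, camera, adjusted p = 3.35e-07). With an estimated correlation the adjusted p was 0.0882. APCDD1 rose from 52.6 ± 0.84 to 167 ± 0.199, NKD1 from 29.6 ± 1.76 to 116 ± 1.48, LEF1 from 7.09 ± 0.169 to 21.2 ± 0.656 and AXIN2 from 64 ± 0.128 to 110 ± 0.601. APCDD1, NKD1, AXIN2 and DKK1 are known as feedback inhibitors of the pathway, and LEF1 is one of its transcription factors. The falls were the stem cell receptor LGR5 (20.8 ± 1.06 to 10.8 ± 0.512), CRIPTO (-0.75, formerly TDGF1), FZD7 (-0.48) and MYC (-0.20). The call of MYC ended without vector replicate 1 (limma, adjusted p = 0.11), RNF186 replicate 1 (0.108) or RNF186 replicate 3 (0.0841), and with TPM rescaling (0.0586).

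Genes of the cholesterol synthesis list fell together. Of 24 tested members 22 fell and 2 did not pass, STARD4 (change 0.01) and SC5D (-0.10), with a median of -0.41 (camera, adjusted p = 5.18e-11, and 0.0192 with an estimated correlation). Lanosterol synthase LSS fell from 34.4 ± 1.15 to 18.8 ± 1.72, FDPS from 137 ± 3.17 to 90.7 ± 3.48 and HMGCS1 from 134 ± 5.36 to 90.2 ± 5.76. Heat shock chaperones fell in 13 of 15 cases (median -0.34, camera, adjusted p = 7.24e-08, and 0.0386 with an estimated correlation). The abundant HSPA8 went from 2400 ± 83.1 to 1750 ± 59.1 and HSPA1B from 194 ± 16.4 to 124 ± 9.66, while DNAJA1 (-0.10) and HSPA4 (-0.11) did not pass. With the correction for length and GC content SC5D (-0.18, limma, adjusted p = 0.00148), DNAJA1 (-0.16, 0.00399) and HSPA4 (-0.21, 0.000495) were called lower.

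Proliferation genes were lower, with 16 of 30 members down and CCNE1 up (median -0.21, camera, adjusted p = 4.57e-05, and 0.0386 with an estimated correlation). Adjusted over the list alone, 17 were lower and 2 higher. The mitotic genes CDC20 (65.3 ± 5.38 to 36.7 ± 2.13), CCNB1 (68.8 ± 3.59 to 42.2 ± 1.18), CCNB2 (37.2 ± 0.516 to 22.9 ± 0.655) and PLK1 (52.7 ± 2.23 to 33.6 ± 0.648) led the list. The rise of CCNE1 (0.17) held without vector replicate 1 but ended without vector replicate 2 or 3 or any RNF186 replicate (limma, adjusted p = 0.0507 to 0.159), with median scaling (0.0514), quantile normalization (0.0765) and the length and GC correction (0.0533). Targets of p53 had 13 falls and 3 rises among 22 members (median -0.22, camera, adjusted p = 0.00557, and an adjusted p of 0.0991 with an estimated correlation), or 14 and 4 adjusted over the list alone. MDM2, which restrains p53, fell from 78.3 ± 3.16 to 54.5 ± 3.01 and FAS from 16.1 ± 0.305 to 12 ± 0.767, while TP53INP1 (0.40), GADD45A (0.30) and BTG2 (0.29) rose. Ribosomal protein genes fell slightly in 22 of 35 cases (median -0.19, camera, adjusted p = 7.36e-06), and in 26 adjusted over the list alone. With an estimated correlation their adjusted p was 0.45.

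Genes of the unfolded protein response rose in 20 of 32 cases (median 0.29, camera, adjusted p = 2.29e-06, and 0.0372 with an estimated correlation). The folding proteins of the endoplasmic reticulum CALR (527 ± 6.77 to 757 ± 25.3), PDIA3 (248 ± 2.56 to 387 ± 13) and HYOU1 (55.6 ± 0.361 to 86.1 ± 2.4) were among them. The transcription factor ATF4 (314 ± 2.99 to 230 ± 4.42) and its target TRIB3 (-0.37) fell, while another ATF4 target, ASNS, rose (0.55). Autophagy genes rose in 16 of 30 cases, BNIP3 (24.7 ± 0.17 to 45 ± 3.35), BNIP3L, OPTN and GABARAPL1 in front, and ATG16L1 fell (-0.31). The list median was 0.18 (camera, adjusted p = 0.000419, and an adjusted p of 0.0504 with an estimated correlation), and adjusted over the list alone 16 rose and 3 fell. Hypoxia genes rose in 14 of 21 cases, with BNIP3 on both lists, VEGFA from 69.8 ± 1.16 to 94.2 ± 0.574 and P4HA1 from 36.6 ± 0.445 to 52.4 ± 2.35. CA9, a classical hypoxia target, went the other way (30.6 ± 1.88 to 4.17 ± 0.372). The hypoxia list had a median of 0.22 (camera, adjusted p = 0.000419, and an adjusted p of 0.0504 with an estimated correlation).

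Antigen presentation genes rose in 7 of 17 cases and the other 10 did not pass (median 0.25, camera, adjusted p = 0.000574, and an adjusted p of 0.26 with an estimated correlation). CD74 rose from 17 ± 0.999 to 116 ± 3.08, HLA-DMA from 4.03 ± 0.297 to 10.5 ± 0.219 and B2M from 535 ± 2.16 to 848 ± 24.6. Interferon response genes had 12 rises and 2 falls among 26 members, 13 and 2 adjusted over the list alone (median 0.15, camera, adjusted p = 0.00449). Their adjusted p was 0.325 with an estimated correlation and 0.103 among genes with a mean of at least 5 FPKM. IFI27 rose from 73.9 ± 3.18 to 142 ± 10.8 and IFI6 from 5.01 ± 0.63 to 14.4 ± 0.645, while MX1 (-0.33) and IFITM1 (-0.24) fell. The call of IFITM1 ended without vector replicate 1 (limma, adjusted p = 0.0618) or RNF186 replicate 1 (0.0616).

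Markers of intestinal cell types moved in both directions. Of 17 goblet cell genes 7 fell, among them AGR3 (35.5 ± 2.68 to 16.7 ± 1.96), TFF3 (52.8 ± 4.08 to 27 ± 4.92) and MUC5B (9.27 ± 0.197 to 4.17 ± 0.401). The 5 that rose were MUC6 (0.39), MUC13 (0.29), CREB3L1 (0.29), MUC5AC (0.27) and AGR2 (0.17), and the list as a whole did not pass (camera, adjusted p = 0.266). CREB3L1 lost its call with quantile normalization (limma, adjusted p = 0.0569) and without vector replicate 2 (0.0557), as did AGR2 without that library (0.0931), which also lost it without RNF186 replicate 3 (0.0601) and with the correction for length and GC content (0.128). Of 16 absorptive enterocyte genes 7 fell, FABP1 most (6.72 ± 1.06 to 1.63 ± 0.379), and 5 rose. The rises were the adhesion molecules CEACAM5 (50.9 ± 0.667 to 128 ± 3.09), CEACAM6 (33.1 ± 1.64 to 65.5 ± 3.94) and CEACAM7 (1.58 ± 0.223 to 6.6 ± 0.324), the glucose transporter SLC5A1 (0.95) and CDX2 (0.21). The median was -0.14 and the mean 0.00 (camera, adjusted p = 0.665). The call of CDX2 ended without vector replicate 2, vector replicate 3 or RNF186 replicate 1 (limma, adjusted p = 0.058 to 0.0842). None of the 19 enteroendocrine genes with values reached a mean of 1 FPKM.

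Among 30 genes of epithelial junctions and keratins 7 rose and 10 fell (camera, adjusted p = 0.418). CTNNB1, which encodes β-catenin, rose from 226 ± 2.63 to 376 ± 2.86, and the intestinal cadherin CDH17 fell from 116 ± 0.604 to 88.9 ± 3.37. Of 10 mesenchymal genes TGFBI (1.07), MMP2 (1.09), MMP14 (0.60) and COL6A1 (0.35) rose, and TAGLN (-0.47), CCN2 (-0.39) and S100A4 (-0.21) fell. The median of that list was -0.12 and its mean 0.16 (camera upward, adjusted p = 0.631). CCN2 lost its call without vector replicate 1, vector replicate 3 or RNF186 replicate 3 (limma, adjusted p = 0.0837 to 0.0949), and S100A4 without vector replicate 2 or RNF186 replicate 3 (0.0674 and 0.0604) and with quantile normalization (0.0517).

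Apoptosis genes had 7 rises, led by PMAIP1 (6.66 ± 0.329 to 12.9 ± 0.391) and BIRC3 (5.6 ± 0.119 to 10.2 ± 0.884), and 3 falls, BAK1 (-0.36), BAX (-0.35) and MCL1 (-0.15), among 23 members (camera, adjusted p = 0.255). MCL1 kept its call only when all 6 libraries were used or RNF186 replicate 3 was left out (limma, adjusted p = 0.0573 to 0.144 without any 1 vector replicate or RNF186 replicate 1 or 2, 0.141 with quantile normalization and 0.186 with TPM rescaling). Feedback genes of MAPK signalling had 11 rises, led by PHLDA1 (0.44) and ETV5 (0.50), and 5 falls, EREG (-0.26), SPRY1 (-0.26), EPHA2, MYC and SPRY2 (-0.17), among 22 (camera, adjusted p = 0.099). The calls of SPRY1 and SPRY2 each ended without 1 of 3 libraries, vector replicate 3 and RNF186 replicate 1 for both, vector replicate 1 for SPRY1 and vector replicate 2 for SPRY2 (limma, adjusted p = 0.0565 to 0.0705), and SPRY2 also lost it with TPM rescaling (0.0894). MYC lost it without vector replicate 1 or RNF186 replicate 1 or 3 (0.0841 to 0.11). Of 19 immediate early genes 8 fell, KLF2 (-0.50) and KLF6 (-0.26) among them, and NR4A3 (0.72), EGR1 (0.39) and BTG2 rose (camera, adjusted p = 0.238). EGR1 lost its call without vector replicate 3, RNF186 replicate 1 or RNF186 replicate 3 (limma, adjusted p = 0.0603 to 0.0632) and with quantile normalization (0.0667).

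Glycolysis genes went both ways, with 5 of 20 up and 4 down, and 6 and 6 adjusted over the list alone (camera, adjusted p = 0.917). ENO2 (0.34), HK2 (0.30), LDHA (0.25), SLC2A1 (0.20) and HK1 (0.16) rose, and ALDOC (-0.71), GAPDH (-0.28), PGK1 (-0.28) and ENO1 (-0.20) fell. SLC2A1 lost its call without any 1 vector replicate, HK1 without vector replicate 1 or 3 or RNF186 replicate 1, and GAPDH and ENO1 without vector replicate 1 or 2 or RNF186 replicate 1 or 3 (limma, adjusted p up to 0.114). With quantile normalization the change of GAPDH was only -0.04 (limma, adjusted p = 0.601) and that of ENO1 -0.07 (0.179), so these falls depend on the scaling. Targets of NRF2, the regulator of oxidative defence, had 8 falls and 6 rises among 24 members (median -0.05, mean -0.52, camera, adjusted p = 0.0489, and an adjusted p of 0.45 with an estimated correlation). Metallothioneins made up 5 of the 8 falls, and AKR1C3 rose from 6.11 ± 0.744 to 17 ± 1.9. The list lost its call without vector replicate 1 (adjusted p = 0.0616) or RNF186 replicate 2 (0.0802). Of 6 replication histones H1-2 (-0.91), H2AC20 (-0.80), H2BC5 (-0.44) and H2BC12 (-0.32) fell and H2BC21 (0.34) rose (camera, adjusted p = 0.0459, and an adjusted p of 0.191 with an estimated correlation). With the correction for length and GC content the adjusted p of H2BC12 was 0.245 (limma). The call of the list ended without vector replicate 2 (adjusted p = 0.0602) or RNF186 replicate 2 (0.0802). Of 15 RING-type ligases 9 were higher, RNF186 itself among them with RNF145 (0.55), ZNRF3 (0.31) and RNF43 (0.28), and RNF167 was lower (-0.14). The adjusted p of this list was 0.00683 by camera, 0.0549 without RNF186 and 0.191 with an estimated correlation. The call of RNF167 ended without vector replicate 1 or 3 or RNF186 replicate 1 or 3 (limma, adjusted p = 0.0747 to 0.0856), with quantile normalization (0.141) and with TPM rescaling (0.115).

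**Figure D4:**
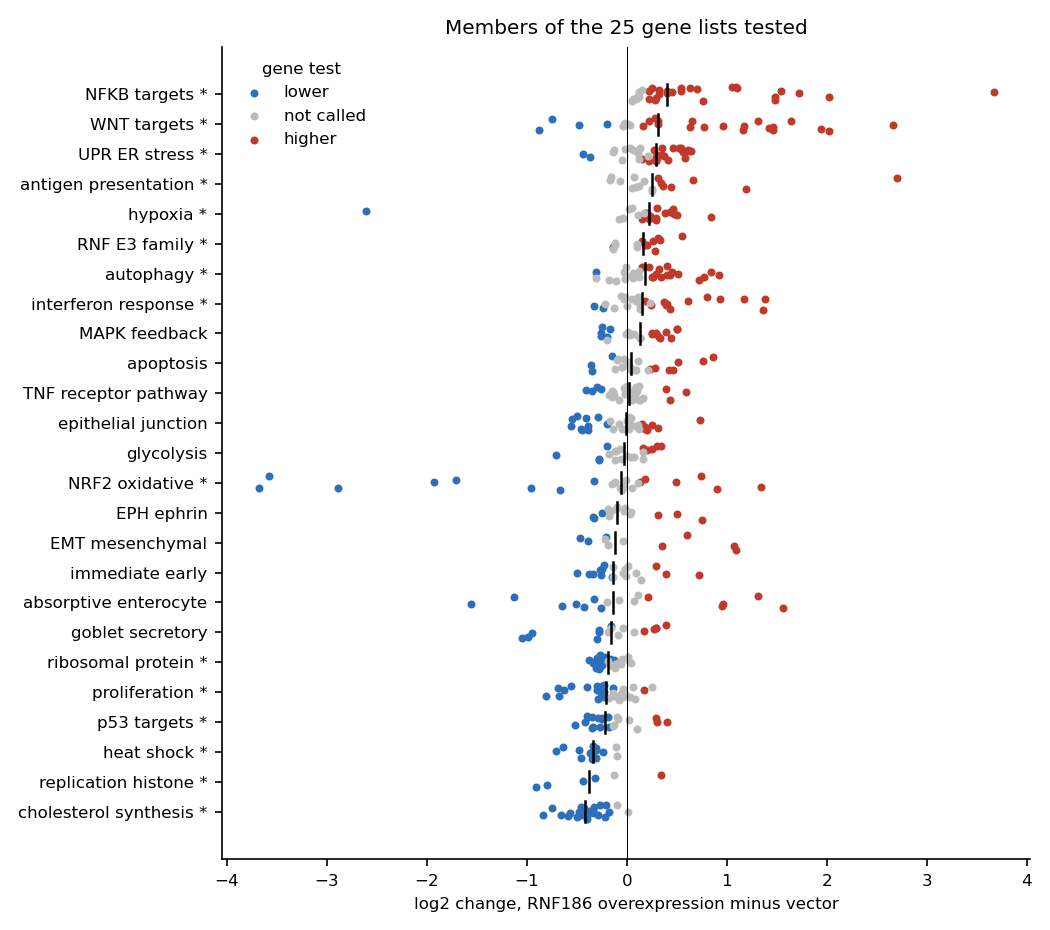
Log2 change of each tested member of 25 gene lists (RNF186 overexpression minus vector), coloured by the test of the gene, with a black bar at the median and an asterisk on lists with a camera adjusted p under 0.05. RNF186 itself is left out of the points, and the NF-κB and cholesterol synthesis lists lie at opposite ends with medians of 0.40 and -0.41.

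Camera called 15 of the 25 lists, and 5 of these held with an estimated correlation, namely NF-κB targets, cholesterol synthesis, heat shock, proliferation and the unfolded protein response. Counts adjusted over the list alone equalled those over all genes for every list where no second count is given. Markers of other cell types were low or moved both ways. All 10 fibroblast genes stayed under 1 FPKM in every library, COL5A1 being highest over both groups together at 0.08 ± 0.02 and 0.06 ± 0.02. Of 11 leukocyte genes CD68 fell from 25.8 ± 2.58 to 20.2 ± 1.28 and CD14 from 1.99 ± 0.186 to 1.31 ± 0.188, LYZ rose from 15.6 ± 0.86 to 19 ± 0.422, and PTPRC was 2.08 ± 0.189 against 2.13 ± 0.284. Of 10 endothelial genes ESAM fell from 1.67 ± 0.115 to 1.04 ± 0.165 and ERG was 1.59 ± 0.0651 against 1.55 ± 0.117. Of 15 retina genes 13 stayed under 1 FPKM in every library, and PDE6A was highest at 1.5 ± 0.186 and 1.48 ± 0.104. Of 11 liver and kidney genes SERPINA1 rose from 4.98 ± 0.11 to 7.68 ± 0.505 and PAX8 fell from 1.92 ± 0.256 to 1.38 ± 0.159. The call of PAX8 ended without vector replicate 1 or 2 or RNF186 replicate 1 or 3 (limma, adjusted p = 0.095 to 0.108).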

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

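Of 203 named genes 171 kept their call or lack of one in all 18 settings run for the gene test, and 0 calls reversed. Sign changes of uncalled genes were not counted. Leaving out 1 library ended the calls of 27 named genes (limma, adjusted p up to 0.177), and MT4 gained a call, as lower, without RNF186 replicate 2 (adjusted p = 0.00458), with array weights (0.00342) and with the replicate block (0.0268). The correction for length and GC content was chosen after seeing the data. It gave 5708 calls, 43% of them higher, and ended the calls of AGR2, H2BC12, GARS1, PSMD10, COX7B, CCNE1 and SLC30A1 while SC5D, DNAJA1 and HSPA4 gained one, all lower. Quantile normalization ended those of CCNE1, MCL1, CREB3L1, S100A4, EGR1, ENO1, GAPDH and RNF167, TPM rescaling those of MYC, MCL1, SPRY2 and RNF167, and median scaling those of CCNE1, GARS1 and COX7B. Testing without a filter ended those of MYC, CCNE1, MCL1, CCN2, SLC2A1, ENO1, GAPDH, MARS1, GARS1 and COX7B, and leaving out the trend those of MCL1, ENO1, RNF167, MARS1, GARS1, PSMD10 and COX7B. The cause was not tested. Leaving out 1 library gave 3160 to 5669 calls, 1720 to 2724 higher and 1435 to 2945 lower, the lowest count of lower genes being without RNF186 replicate 3 and the highest without RNF186 replicate 2. A log2 change of at least 1 left 191 genes, 157 higher and 34 lower, and an adjusted p under 0.01 left 2586, with 1465 higher and 1121 lower, as a stricter threshold must. Array weights gave 6376 calls. TPM rescaling gave 4361 calls, 63.1% of them higher. Leaving out repeated symbols changes nothing, since there are none. With the replicate number as a replicate block 4037 genes were called, and MYC, CCNE1, MCL1, HK1, RNF167, SLC30A1, MARS1, GARS1, PSMD10 and COX7B were not. Same-numbered libraries had deviations from their group mean correlated at -0.27, -0.07 and 0.25 across genes. Differently numbered libraries were not compared, so these values do not decide whether the numbers pair the dishes.

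Among the lists, NF-κB targets (adjusted p from 4.28e-13 to 0.0192 over 19 camera alternatives), cholesterol synthesis, heat shock, proliferation and the unfolded protein response passed in each. An estimated correlation ended 10 calls: WNT targets 0.0882, p53 targets 0.0991, autophagy 0.0504, hypoxia 0.0504, interferon response 0.325, antigen presentation 0.26, NRF2 targets 0.45, ribosomal proteins 0.45, histones 0.191 and RING ligases 0.191. For WNT targets the other alternatives reached down to 1.7e-08. The NRF2 list (0.0198 to 0.45) also missed the threshold without a filter (0.0508), at a mean of 5 FPKM (0.072), with quantile normalization (0.157), without a trend (0.0527), with array weights (0.0987), after the length and GC correction (0.0942) and without its member that changed most (0.166), and leaving out 1 library gave 0.0272 to 0.0802. The histone list (0.0165 to 0.191) missed it without a filter (0.0502), at a mean of 5 FPKM (0.125), without a trend (0.0507), with array weights (0.071), after the length and GC correction (0.15) and without its top member (0.166), and leaving out 1 library gave 0.0165 to 0.0802. The interferon list reached 0.103 at a mean of 5 FPKM, and the RING ligases 0.0549 without RNF186. The cause was not tested. Fry, which asks whether a list moves on balance without comparing it with other genes, called apoptosis (0.00284, up), goblet genes (0.02, down), junctions (0.00537, down), mesenchymal genes (0.00759, up) and MAPK feedback (0.00258, up), and gave absorptive enterocyte genes the opposite direction (0.00886, up). Its test of change in either direction passed all 25 lists (adjusted p up to 0.0321), so a pass there sets no list apart. Those that camera had not called were the TNF pathway (0.000526), ephrins (1.4e-05), apoptosis (4.28e-05), goblet (1.26e-05), absorptive (7.84e-07), junction (2.14e-05), mesenchymal (8.32e-06), MAPK feedback (3.36e-06), immediate early (0.000103) and glycolysis genes (1.27e-05). A count-based edgeR test and a robust prior for the lists were not run, because there are no counts and camera has no such prior. Depth is unknown, so it cannot be said how far low genes are limited by it.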

Other observations

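Tests chosen only after the result was seen were those of all gene families named here, of the correction for length and GC content, of reads moved between metallothioneins, of blood or stromal cells, of differences between lines and of lower RNF186 in replicate 2. Of 8 gene families added to the fixed lists 6 passed camera with its preset correlation, and none with an estimated correlation. Some of their members were also on a fixed list, such as metallothioneins on that of NRF2 and DKK1, NOTUM and BMP4 on that of WNT targets. Of 59 secreted ligands and antagonists of the WNT, FGF, Hedgehog and BMP pathways with values, 19 were tested. Of these 9 rose and 10 did not pass (median 0.13, camera, adjusted p = 1.41e-05, and an adjusted p of 0.091 with an estimated correlation). A member low in vector cells, such as DKK1, could reach the level for testing through its own rise. Besides SHH, DKK1, DKK4 and FGF20 the genes that rose were NOTUM (3.93 ± 0.418 to 19.1 ± 2.93), WNT16 (1.46 ± 0.104 to 8.54 ± 0.996), FGF19 (4.85 ± 0.209 to 19.7 ± 0.793), FGF9 (3.81 ± 0.11 to 6.78 ± 0.28) and BMP4 (265 ± 8.38 to 309 ± 12). Fatty acid synthesis genes fell in 9 of 17 cases (median -0.19, camera, adjusted p = 0.00228, and an adjusted p of 0.091 with an estimated correlation). Adjusted over the list alone 10 fell and 2 rose. The falls were led by the desaturase SCD (78.7 ± 3.22 to 31.1 ± 0.99), FADS2 (44.8 ± 2.03 to 27 ± 2.44), FASN (66 ± 2.54 to 41.7 ± 6.62) and the regulator SREBF1 (30.8 ± 1.03 to 20.1 ± 2.7), while ME1 rose (0.49). S100 proteins and annexins fell in 12 of 20 cases (median -0.30, camera, adjusted p = 1.04e-05, and an adjusted p of 0.091 with an estimated correlation), and in 13 adjusted over the list alone. ANXA1 went from 122 ± 5 to 50.4 ± 1.4, S100A10 from 89.3 ± 6.05 to 44.6 ± 1.99 and S100A16 from 292 ± 15.3 to 169 ± 17.8, while ANXA5 rose (0.25).

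Subunits of the CCT chaperonin fell in 7 of 8 cases (median -0.23, camera, adjusted p = 0.000325, and an adjusted p of 0.091 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 20 of 72 cases (median -0.08, camera, adjusted p = 0.00239, and an adjusted p of 0.452 with an estimated correlation). Adjusted over the list alone 18 fell and 3 rose. Over all genes NDUFS5 (0.32), NDUFA12 (0.19), ATP5MC2 (0.19) and COX7B (0.13) rose. Among 20 tRNA synthetases 7 fell and WARS1 (0.38), EPRS1 (0.25), LARS1 (0.21), GARS1 (0.15) and MARS1 (0.15) rose (camera, adjusted p = 0.206), and among 37 proteasome genes 6 fell and PSMA1 (0.17) and PSMD10 (0.14) rose (camera, adjusted p = 0.448). Adjusted over the list alone, none of the proteasome genes passed. NDUFA12 lost its call without vector replicate 2 (limma, adjusted p = 0.0528), ATP5MC2 without vector replicate 2 or 3 or RNF186 replicate 3 (0.0636 to 0.0871) and PSMA1 without vector replicate 3 or RNF186 replicate 1 or 3 (0.0556 to 0.0768). COX7B lost it without vector replicate 2 or 3 or RNF186 replicate 1 or 3 (0.108 to 0.177), GARS1 (0.0543 to 0.173) and PSMD10 (0.0517 to 0.132) without any 1 vector replicate or RNF186 replicate 1 or 3, and MARS1 without any 1 of the 6 libraries (0.0605 to 0.168). With the correction for length and GC content the adjusted p of GARS1 was 0.105, of PSMD10 0.148 and of COX7B 0.24.

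The fall of the metallothioneins covered 9 of 11 members (camera, adjusted p = 2.15e-11, and an adjusted p of 0.091 with an estimated correlation), and MT3 and MT4 were not called, although MT4 was called lower under some alternatives, among them without RNF186 replicate 2 (limma, adjusted p = 0.00458) and with array weights (0.00342). A loss of fragments from short transcripts is argued against by 151 genes matched on length, GC content and mean FPKM, whose median change was -0.05 (5th to 95th percentile -0.41 to 0.76) against -2.89 for the 9 genes. Reads moved between paralogs would leave the family sum in place, yet it went from 2720 ± 240 to 425 ± 22.8, a ratio of 6.39. Lower activity of the zinc-sensing factor MTF1 was predicted to lower the zinc exporter SLC30A1 as well, which instead had a change of 0.19 (SE 0.056). That call ended without vector replicate 2 or 3 or RNF186 replicate 1 or 3 (limma, adjusted p = 0.0743 to 0.0916). After the length and GC correction the change of SLC30A1 was 0.08 (limma, adjusted p = 0.297), still not a fall. The prediction was not met, but 1 target gene cannot decide whether MTF1 was less active. A difference between the stable lines unrelated to RNF186 cannot be told apart from an effect of RNF186, because the series has 1 RNF186 line.

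The rise of the NF-κB and WNT target lists was not removed by the correction for length and GC content, after which their adjusted p-values were 7.58e-13 and 1.2e-07 (camera), although without that correction the WNT list had an adjusted p of 0.0882 with an estimated correlation. A large share of leukocytes or endothelial cells in the RNF186 cultures is argued against by their markers, of which 1 of 6 tested was higher and 3 were lower. These were 4 leukocyte and 2 endothelial genes, and no fibroblast gene reached the level for testing. Of the markers with values, 7 of 11 leukocyte and 8 of 10 endothelial genes stayed under 1 FPKM in every library. Because CD68 and LYZ were expressed in vector cells too, a small share of such cells cannot be excluded. An earlier bound, that such markers stay under 1 FPKM, was not met, since CD68 was 25.8 ± 2.58 and 20.2 ± 1.28 in vector and RNF186 cells, LYZ 15.6 ± 0.86 and 19 ± 0.422 and PTPRC 2.08 ± 0.189 and 2.13 ± 0.284, and the bound used was set after these levels were known. As with the metallothioneins, 1 line per group leaves a difference between lines open, so that the rise of TNF and NF-κB targets may belong to RNF186 or to the line.

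RNF186 replicate 2 stood apart from its fellow replicates. Length and GC content together accounted for 0.525 of the variance across genes of its difference from replicates 1 and 3, GC content alone for 0.524, while for replicate 1 minus replicate 3 both accounted for 0.00345. This is consistent with a GC-dependent bias in that library. RNF186 expression was not lower in replicate 2, at 577 FPKM against 451.72 and 484.61 in replicates 1 and 3. After the length and GC correction its log2(FPKM + 1) was 9.11 in replicate 2 against 8.9 and 9. A mixture with vector cells stays open, because RNF186 was highest in replicate 2 while genes lay slightly toward the vector level there. After the length and GC correction, replicate 2 minus replicate 3 had a slope of -0.055 on replicate 1 minus vector across all tested genes except RNF186, and replicate 2 minus replicate 1 one of -0.04 on replicate 3 minus vector, with shares of the variance of 0.019 and 0.0098.

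Of the 10 splits of the 6 libraries into groups of 3, 1 gave as many called genes as the real one, namely the real split itself with 4509. The highest count of the other splits was 0 by limma, with 42 to 1016 genes at an unadjusted p under 0.05. Each of the other splits mixes vector and RNF186 libraries in both groups, so a difference between the lines widens the spread within groups. Low counts there follow from that and give no further support. The 10 splits are too few for a share under 0.05.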
